A study of Mus musculus with 41 samples.

How the data were processed

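Mouse primary cortical neurons at 10 days in vitro were compared by chromatin immunoprecipitation with sequencing. The groups, taken from the sample labels before the data were examined, are the antibody target, the genotype (LSD1n WT, LSD1n KO, wild type, or neurons with Flag-tagged LSD1n or LSD1c) and 0 h or 1 h in 55 mM KCl. Of the 41 samples of the series, 27 have a list of peaks and were used, in 26 groups. The 10 GRO-seq and 4 RNA-seq samples are not analysed here.

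The submitters' processing notes name Bowtie and HOMER without versions, and build mm9. Per the file headers, the authors called histone regions by stitching peaks of 500 bp with a minimum distance of 1250 bp. Sites of Pol II and LSD1 were called at a fixed size of 200 bp, a minimum distance of 500 bp and 4-fold more tags than the surrounding 10 kb. All lists used a false discovery rate of 0.001, fragments of 150 bp and 1 tag per position, and the headers name no control library. The deposited unit is genomic positions: the start and end of each peak, in bp of mm9. The deposited score is 1 in every entry, so peaks were ranked by width for histone marks and by order in the list for sites of fixed size. Total tags and tags in peaks were read from the headers; total tags ranged from 6990017 to 34859557 per library.

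From these lists the number of peaks, the covered length, and the share of tags in peaks were computed with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1; figures used matplotlib 3.10.9. There are 24 comparisons of peak numbers: 9 of genotype, 12 of KCl time, 2 of isoform and 1 between the 2 H4K20me1 WT lists at 1 h. For genotype and KCl, the mean of those 2 lists was used. Ratios have exact conditional Poisson intervals and shares exact Clopper-Pearson intervals at 95%. As all groups but 1 have 1 list, no test between groups was run. Peaks were counted as shared when they overlapped by at least 1 bp, and each share was set against the mean of 1000 circular shifts of the other list within its chromosomes (200 for pairs of marks at 0 h). The calculation was tested on simulated lists placed uniformly at random: planted overlaps of 0%, 10% and 30% came back as -0.05%, 9.93% and 30.0% above the shifted background. No clustering of peaks was simulated, so this checks the calculation and not how well the shifted background suits the deposited lists.

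The positions named are the 3 highest-ranked peaks shared by both lists of a comparison and the 3 highest-ranked found in 1 list alone, and the text gives some of them. This rule was set before the data were examined. For sites of fixed size the rank by order in the list was chosen after the data were seen. The regions of chromosome X and Y discussed in the closing section were chosen after their values were seen. Positions count from 1. No mm9 gene annotation was used here, so no gene is named and the planned gene lists were not run. Regions called with all 8 targets (434 regions, 2.98 Mb) were kept in the comparisons of peak numbers and overlaps, and leaving them out is an alternative. They were left out of the classes of sites by isoform, the search for earlier sites and the densities of sites in H4K20me1 regions, and keeping them is an alternative there. To leave them out, each peak that itself overlaps a peak of all 8 targets was dropped. Other peaks inside the 434 regions stayed. The other alternatives were autosomes only, merging peaks within 5 kb, covered length, the upper part of the peaks by width, the share of tags in peaks, other overlap rules, equal list lengths and local shifts of 100 kb to 1 Mb. Prefixes of the sample titles were taken as possible batches. The genotype inside all 4 deposited Pol II lists is the opposite of the labels; groups follow the labels.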

Results

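The series asks where LSD1 and its neuronal isoform LSD1n bind, and how histone marks differ, in cultured mouse cortical neurons with and without LSD1n. The neurons were kept 10 days in vitro and bathed in 55 mM KCl for 0 h or 1 h, which depolarizes them. Chromatin immunoprecipitation followed by sequencing gave 27 lists of called regions (peaks) on build mm9: 15 for histone marks and 12 for Pol II, LSD1 and Flag-tagged LSD1n or LSD1c. The lists held between 940 peaks (Flag-LSD1n at 0 h) and 62945 peaks (H3K4me1, LSD1n KO at 1 h). The share of all sequenced tags inside peaks ran from 0.0806% (Flag-LSD1n at 0 h) to 19.6% (H4K20me1, KO at 0 h). All groups but 1 hold 1 library, so no difference between groups was tested. Bracketed ranges are 95% exact intervals and cover counting error only. The group with 2 libraries is H4K20me1 in WT at 1 h, and nothing in the labels says that these came from separate cultures.

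**Figure D1:**
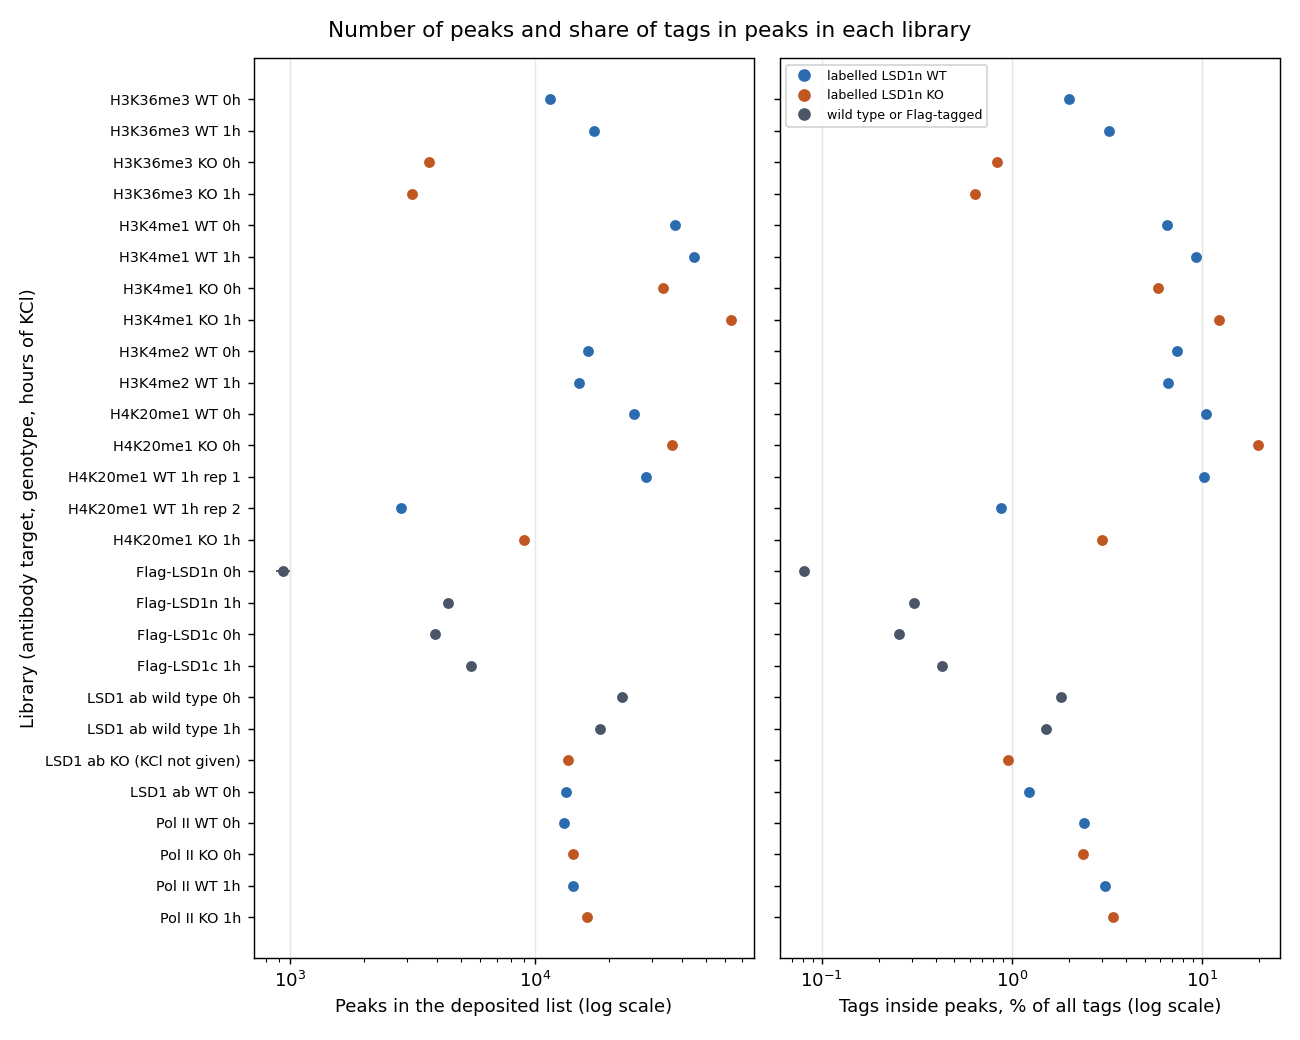
Peaks per deposited list (left, log scale) and tags inside peaks as a percent of all tags (right, log scale) for each of the 27 libraries, with 95% intervals for counting error that are mostly narrower than the points. The Flag-LSD1n library at 0 h is lowest on both axes, and the 2 H4K20me1 WT libraries at 1 h lie 10-fold apart in peaks.

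At rest (KCl 0 h), H4K20me1 covered more of the genome in the LSD1n KO library than in WT. The KO list had 36291 regions over 93.6 Mb and the WT list 25429 regions over 49.9 Mb, a log2 ratio of region numbers of 0.51 (0.49 to 0.54), or 1.43-fold. With regions within 5 kb merged the log2 ratio was 0.27. Regions wider than 10 kb numbered 1814 in KO and 698 in WT. The KO library also had 19.6% of its tags in regions, against 10.5% in WT, from 21256742 and 18494273 tags in all. Both libraries share a title prefix. Most WT regions were kept: 77.4% (76.9 to 77.9) overlapped a KO region, 12.9 times the share for shifted lists (8.12 for shifts of 100 kb to 1 Mb), while 36.5% (36 to 37) of KO regions overlapped a WT region. The share of KO regions was 16.7% at an overlap of 50% of the region and 49.0% with equal numbers of the widest regions.

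Wider regions were shared more often, while the excess in KO was not confined to narrow ones: among regions wider than the pooled median the log2 ratio was 0.62. Among the widest of 5 equal parts of the KO list 93.6% of regions were also in WT, and among the narrowest of 5 equal parts 6.70%. An overlap of 1 bp is met more easily by a wide region, with median widths of 5755 and 501 bp in these parts. No shifted share was computed for each part, so how much of the gradient comes from width itself is unknown. The 23041 KO regions without a WT counterpart had a median width of 629 bp, covered 20.9 Mb, and none was wider than 10 kb. The 13250 shared KO regions had a median width of 2980 bp and covered 72.6 Mb, more than the whole WT list. In WT alone, 5745 regions were found, 3.51 Mb in all. The widest shared WT regions lay on chromosome 13 (100195030 to 100284178), chromosome 11 (3026816 to 3100138) and chromosome 2 (6623186 to 6694002). Each was covered in KO over at least 99.7% of its length. The widest KO regions without a WT counterpart were on chromosome 18 (36538978 to 36548192), chromosome 9 (14830378 to 14839474) and chromosome 7 (140159120 to 140168152), 9.21, 9.10 and 9.03 kb wide. None of these 3 was called in KO or in WT replicate 2 at 1 h. In WT replicate 1 at 1 h, 22.7%, 5.51% and 26% of their length was called. The 3 widest regions found in WT alone were all on chromosome Y, where the KO list had no region at all.

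**Figure D2:**
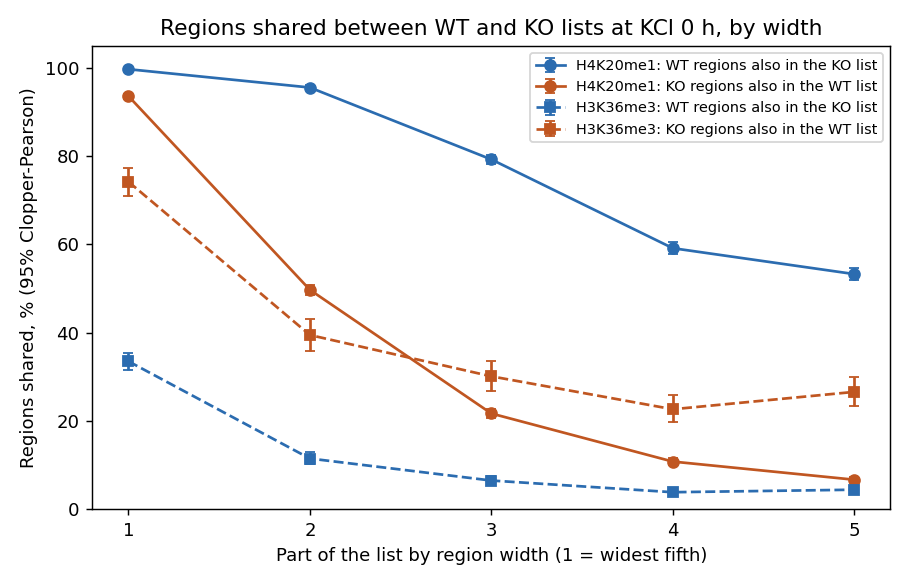
Percent of regions that overlap a region of the other genotype at KCl 0 h, for 5 equal parts of each list in order of width (1 is the widest), with 95% Clopper-Pearson intervals. For H4K20me1 the share of KO regions also in WT drops from 93.6% in the widest of 5 equal parts to 6.70% in the narrowest, while WT regions stay at 53.3% or above. Overlap was counted at 1 bp, which favours wide regions, and no shifted share was computed for each part.

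After 1 h of KCl the H4K20me1 comparison had no fixed direction. The 2 WT lists held 28453 and 2844 regions, 10-fold apart, with 10.2% and 0.881% of tags in regions. The KO list, with 9022 regions, lay between them, at 0.317 of replicate 1 and 3.17 times replicate 2. Against the mean of both WT lists the log2 ratio was -0.79, and against the mean of their log2 numbers 0.004; the SD between the log2 numbers was 2.35 (n = 2). Of the regions of replicate 2, 81.2% (79.7 to 82.6) were in replicate 1, and 5.20% (4.94 to 5.46) of replicate 1 were in replicate 2 (0.836% at an overlap of 50% of the region, 31.2% with equal numbers of the widest regions). Of the KO regions 75.8% (74.9 to 76.7) were in replicate 1, and 15.3% (14.9 to 15.7) of replicate 1 were in KO (4.003% and 38.1% in the same alternatives). Replicate 2 and KO share a title prefix, and within it the KO list was the longer; replicate 1 has another prefix.

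Between 0 h and 1 h the H4K20me1 list of the KO libraries fell by 2.01 on the log2 scale, from 36291 to 9022 regions. The share of tags in regions went from 19.6% to 2.98%, and 85.6% (84.8 to 86.3) of the 1 h regions were already called at 0 h. The widest KO region, on chromosome 9 (49460056 to 49604658, 145 kb), was 1 block at 0 h. At 1 h it was called in 24 pieces that covered 60.7% of it; WT at 0 h covered 80.4%, WT at 1 h 79.1% (replicate 1) and 13.3% (replicate 2). In WT the log2 ratio of 1 h over 0 h was -0.70 with the mean of both lists and -1.50 with the mean of their log2 numbers, both smaller than that SD. The KO lists at 0 h and 1 h have different title prefixes, so time and prefix cannot be told apart.

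**Figure D3:**
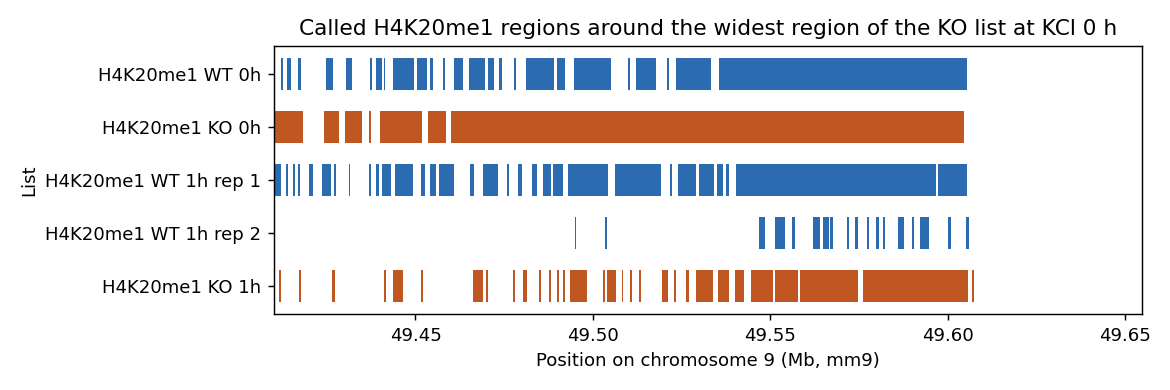
Called H4K20me1 regions (bars) in the 5 lists around the widest region of the KO list at KCl 0 h, on chromosome 9 in Mb of mm9. The region is 1 block of 145 kb in KO at 0 h and is broken into 24 pieces in KO at 1 h.

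H3K36me3, a mark of transcribed gene bodies, was called at fewer regions in KO than in WT at both times. At 0 h there were 3685 regions in KO and 11530 in WT (log2 ratio -1.65, -1.70 to -1.59). At 1 h there were 3166 and 17465 (log2 ratio -2.46, -2.52 to -2.41). The KO libraries had 0.834% and 0.644% of tags in regions, against 1.99% and 3.24% in WT, and 12% (11.4 to 12.6) of WT regions at 0 h were in the KO list. Of the KO regions, 38.6% at 0 h and 47.1% at 1 h were in the longer WT list of the same time. The KO lists shared less with each other: 15.4% of the 0 h regions and 18.4% of the 1 h regions. The shared regions were again the wider ones, with the same limit of a 1 bp overlap that favours wide regions. Of the widest of 5 equal parts of the KO list at 0 h 74.2% was also in WT, and 26.6% of the narrowest. The widest regions called in WT at 0 h and not in KO were on chromosome 7 (86666881 to 86673211), chromosome 2 (157291098 to 157297256) and chromosome 12 (101440394 to 101446366). The WT 1 h list covered 73.9%, 85.0% and 73.5% of them, and the KO 1 h list 23.9%, 8.13% and 33.9%. With KCl the WT list grew (log2 ratio 0.60, 0.57 to 0.63) and the KO list shrank (-0.22, -0.29 to -0.15). All 4 libraries share a title prefix. The KO libraries were less deep, 13147855 and 12572399 tags against 19055899 and 16785574. Whether weaker enrichment or lower depth made the KO lists shorter was not tested.

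H3K4me1, a mark of enhancers, was called at more regions after KCl in both genotypes. Its list grew from 37204 to 44793 regions in WT (log2 ratio 0.27, 0.25 to 0.29) and from 33244 to 62945 in KO (0.92, 0.90 to 0.94). Among regions wider than the pooled median these were 0.49 and 1.39, and by covered length 0.44 and 1.29. By share of tags in regions they were 0.51 and 1.06, and with regions within 5 kb merged 0.21 and 0.76. KO over WT was -0.16 (-0.18 to -0.14) at 0 h and 0.49 (0.47 to 0.51) at 1 h. Of the KO regions at 0 h, 77.9% (77.5 to 78.4) were still called at 1 h. The widest WT 0 h regions without a KO counterpart at 0 h lay on chromosome 8 (15001406 to 15006522), chromosome 16 (18378926 to 18383766) and chromosome 15 (77644219 to 77648863). All 3 were called in KO at 1 h, over 53.3%, 87.5% and 41.6% of their length. The 4 libraries share a title prefix, and the KO 1 h library was the deepest of the 27 used, at 34859557 tags.

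H3K4me2, measured in WT alone, had a slightly shorter list at 1 h and covered less of the genome. The list had 16545 regions at 0 h and 15208 at 1 h (log2 ratio -0.12, -0.15 to -0.09). The log2 ratio was -0.41 by covered length (23.9 Mb to 18.0 Mb) and -0.52 among regions wider than the pooled median, and 79.6% (78.9 to 80.2) of the 1 h regions were called at 0 h. Its libraries were also the shallowest of the 27 used, at 9418008 and 6990017 tags. The median width was 1173 bp at 0 h and 837 bp at 1 h. The widest regions called at 0 h alone were on chromosome 14 (40283526 to 40287446), chromosome 4 (129416429 to 129420333) and chromosome 2 (115895025 to 115898919).

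Pol II lists differed little in length. By the sample labels, the library labelled KO had 14284 peaks and that labelled WT 13142 at 0 h (log2 ratio 0.12, 0.09 to 0.15; -0.0102 by share of tags in peaks), and 16264 and 14358 at 1 h (0.18, 0.15 to 0.21). The names inside all 4 deposited Pol II lists give the opposite genotype to the labels, so the sign of these ratios and every Pol II genotype is uncertain. The number was higher at 1 h in both: 0.13 (0.09 to 0.16) in the libraries labelled WT and 0.19 (0.15 to 0.22) in those labelled KO. By share of tags in peaks these were 0.37 and 0.51, and the 1 h libraries were 1.48 and 1.34 times as deep. In each pair of Pol II lists, between 65.1% and 76.2% of peaks were shared. In the libraries labelled WT, sites called at 1 h alone overlapped H3K4me1 more often than sites called at both times (36.6%, 35.3 to 38.0, against 24.5%, 23.6 to 25.3). They overlapped H3K4me2 less often (40.3%, 38.9 to 41.7, against 58.0%, 57.0 to 59.0), and Flag-LSD1n sites less often (6.02%, 5.37 to 6.72, against 20.9%, 20.1 to 21.8). Flag-LSD1c sites (9.92% against 30.3%) and wild type LSD1 sites (27.2% against 46.1%) gave the same direction, so it was not particular to LSD1n. The strength of the Pol II peaks was not taken into account. The libraries labelled KO gave the same directions: 32.4% against 25.3% for H3K4me1, 34.3% against 56.6% for H3K4me2 and 4.32% against 19.9% for Flag-LSD1n. The first-listed sites at 1 h that no peak of the other genotype overlaps were on chromosome 16 (91648051 to 91648251, within 1 kb of a site of the label KO at 91647734 to 91647934) for the label WT and chromosome 9 (108208158 to 108208358) for the label KO.

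The antibody against LSD1 called similar numbers of sites with and without LSD1n. The LSD1n KO list had 13709 sites and the LSD1n WT list 13400 (log2 ratio 0.03, -0.002 to 0.07), a difference within counting error; with peaks within 5 kb merged it was 0.10. By the share of tags in peaks the order was reversed, 0.959% in KO against 1.23% in WT (log2 ratio -0.36). Of the WT sites, 44.4% (43.6 to 45.3) were called in KO. The KO library was 1.75 times as deep, has another title prefix, and its labels give no KCl time. In wild type neurons the list went from 22663 sites at 0 h to 18457 at 1 h (log2 ratio -0.30, -0.32 to -0.27), and 25.7% (25.1 to 26.4) of the 1 h sites overlapped a 0 h site, or 53.0% when sites within 1 kb were counted. Pol II overlapped 9.01% (8.64 to 9.40) of the sites at 0 h and 30.8% (30.2 to 31.5) at 1 h, each against the Pol II list labelled WT at the same time. LSD1 sites called at 1 h alone lay in the Pol II list of 0 h in 27.3% of cases (26.6 to 28.1), against 7.14% (6.77 to 7.53) of those called at 0 h alone. The first-listed sites shared by both times, on chromosome 9 (35112824 to 35113024) and chromosome 2 (98502813 to 98503013), lie in regions called with all 8 antibody targets.

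Flag-tagged LSD1n was called at few sites at rest and at many more after KCl. Its list grew from 940 to 4438 sites, 4.72-fold (4.40 to 5.07; log2 ratio 2.24, 2.14 to 2.34). The 1 h library was the shallower of the pair, at 26208203 against 31804648 tags. The list of Flag-LSD1c, the other tagged isoform, grew from 3922 to 5480 sites (0.48, 0.42 to 0.54). LSD1n therefore had fewer sites than LSD1c at 0 h (log2 ratio -2.06, -2.17 to -1.96), with a smaller gap at 1 h (-0.30, -0.36 to -0.25). By the share of tags in peaks these log2 ratios were -1.67 and -0.49, and the growth was 1.93 for LSD1n and 0.75 for LSD1c. At 1 h, 34.2% (32.8 to 35.6) of LSD1n sites overlapped an LSD1c site, 360 times the share for shifted lists (193 with local shifts). The share was 21.8% at an overlap of 50% of the site and 60.3% within 1 kb. Sites that overlap peaks of all 8 targets were left out next. At 1 h, sites of both isoforms lay in Pol II peaks more often than sites of LSD1n alone. The shares were 65.9% (63.4 to 68.3) against 43.1% (41.3 to 44.9), while H3K4me2 overlapped 55.5% and 59.4%. At 0 h the Pol II shares of LSD1n sites were 34.4% (29.2 to 39.9) with LSD1c and 33.5% (29.6 to 37.6) alone. With the left-out sites kept they were 44.2% (39.2 to 49.3) and 33.6% (29.7 to 37.7), and at 1 h 67.1% and 43.1%. By definition a site left out overlaps an LSD1c peak and a Pol II peak of some list. Leaving such sites out therefore tends to lower the Pol II share with LSD1c. At 0 h that share went from 171 of 387 sites to 108 of 314. The gap at 0 h thus depends on whether these sites are kept, and which form is nearer the truth was not tested. For LSD1c without the left-out sites the Pol II share was higher with LSD1n at 1 h (68.3% against 58.0% alone) and lower at 0 h (34.0% against 54.9%). With these sites kept the shares were 69.5% against 58.0% at 1 h and 43.2% against 54.9% at 0 h. The first-listed LSD1n sites without an LSD1c site at 1 h were on chromosome 9 (3036353 to 3036553), chromosome 11 (53953536 to 53953736) and chromosome X (121308635 to 121308835), of which the first 2 lie inside regions called with all 8 targets in all 27 lists, so LSD1c has a peak in the same regions. These 2 sites themselves overlap peaks of fewer targets, so they stay among the sites of LSD1n alone. The isoforms have different title prefixes, so isoform and prefix cannot be told apart.

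H3K4me2 was the mark found most often at LSD1 sites, except that Pol II was as frequent or more so for LSD1c and wild type LSD1 at 1 h. At an overlap of 50% of the site the exception did not hold. H3K4me2 then had 52.7% against 41.3% for Pol II at LSD1c sites, and 27.0% against 17.5% at wild type LSD1 sites. For LSD1n at 1 h, 58.5% (57.0 to 59.9) overlapped H3K4me2, 51.3% (49.8 to 52.8) Pol II, 22.0% (20.8 to 23.3) H3K4me1 and 3.81% (3.26 to 4.41) H3K36me3. At an overlap of 50% of the site the Pol II share was 33.2%, and without regions called with all 8 targets the H3K36me3 share was 2.25%; in the first 50% of the site list it was 6.80%. H4K20me1 overlapped 12.7% (11.7 to 13.7) with WT replicate 1 and 7.91% (7.13 to 8.74) with replicate 2. LSD1c at 1 h was close to LSD1n for H3K4me2 (58.3%, 56.9 to 59.6) and H3K4me1 (22.7%, 21.6 to 23.8). It was higher for Pol II (61.2%, 59.9 to 62.5) and lower for H4K20me1 (9.80%, 9.02 to 10.6, with replicate 1). At 0 h the isoforms differed more: H3K4me2 overlapped 64.7% (61.5 to 67.7) of LSD1n and 81.8% (80.6 to 83.0) of LSD1c sites, H4K20me1 23.6% (20.9 to 26.5) and 15.0% (13.9 to 16.1), and H3K36me3 17.2% (14.9 to 19.8) and 4.67% (4.03 to 5.37). Without regions called with all 8 targets the H3K36me3 shares were 11.4% and 3.09%, and in the first 50% of each site list 33.0% and 8.01%. Sites that overlap peaks of all 8 targets made up 7.87% (6.23 to 9.78) of the LSD1n sites at 0 h and 1.74% (1.37 to 2.16) at 1 h. Of the 940 LSD1n sites at 0 h, 48 lay on chromosome Y and 90 on X. For LSD1c at 0 h these were 30 and 66 of 3922. Shares on autosomes alone were not computed, so how much of the 0 h differences rests on X and Y is unknown. All shares of sites overlapping a mark or Pol II were above those of shifted lists. The excess ran from 1.68-fold (wild type LSD1 sites at 1 h with H3K36me3) to 255-fold (LSD1c at 1 h with Pol II). Against shifts of 100 kb to 1 Mb the first of these fell to 0.989.

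**Figure D4:**
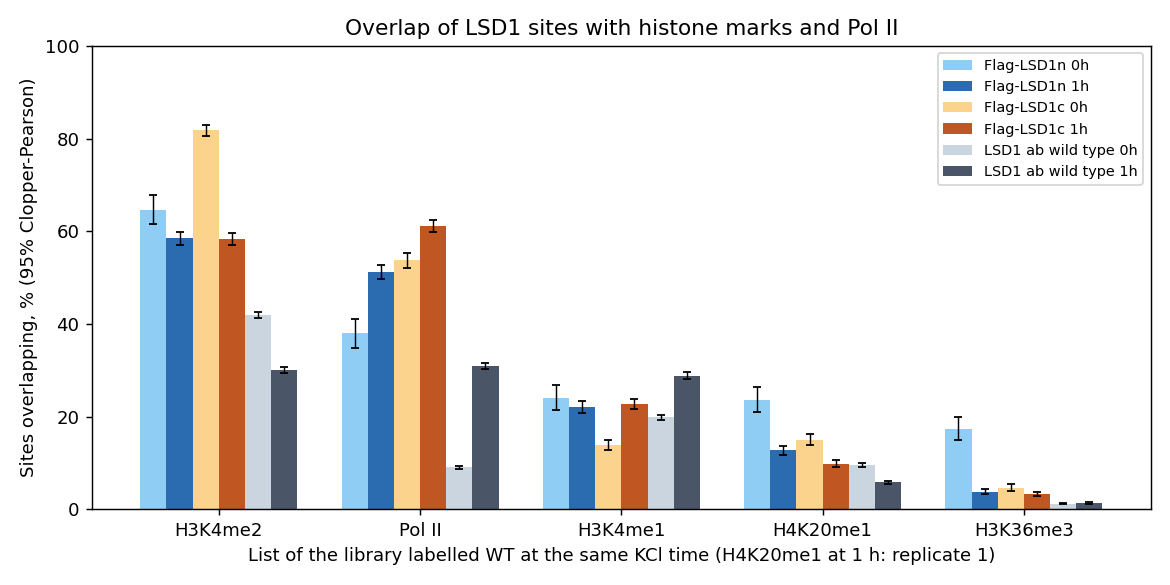
Percent of LSD1n, LSD1c and wild type LSD1 sites at 0 h and 1 h of KCl that overlap each mark or Pol II in the list labelled WT at the same time, with 95% Clopper-Pearson intervals. H3K4me2 overlap is highest for LSD1c at 0 h (81.8%), and Pol II overlap of wild type LSD1 sites goes from 9.01% to 30.8%.

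In WT neurons at rest H3K4me2 overlapped H3K4me1 and Pol II each at more than 50% of its regions. Of H3K4me2 regions 54.1% (53.4 to 54.9) overlapped H3K4me1 and 53.6% (52.8 to 54.3) Pol II, and 72.2% (71.5 to 73.0) of Pol II peaks overlapped H3K4me2. H4K20me1 overlapped H3K4me1 in 27.0% (26.5 to 27.6) of its regions and Pol II in 3.85% (3.62 to 4.09), 3.51 times the share for shifted lists (2.14 with local shifts of 100 kb to 1 Mb). Of H3K36me3 regions 20.4% (19.7 to 21.2) overlapped H4K20me1, 6.80 times the share for shifted lists (3.70 with local shifts), and 1.66% (1.43 to 1.91) Pol II.

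Chromosome X held a larger part of the H4K20me1 list in KO than in WT at rest. It had 412 of the KO regions (1.14%, 1.03 to 1.25) and 171 of the WT regions (0.672%, 0.576 to 0.781). The KO over WT ratio was 2.41 (2.01 to 2.90) on X and 1.42 (1.40 to 1.44) on autosomes. H3K4me1 at 1 h showed the same difference, 2.15 (1.66 to 2.81) on X against 1.40 (1.39 to 1.42). At 0 h its ratios were 0.829 (0.575 to 1.19) and 0.894 (0.880 to 0.907). H4K20me1 at 1 h went the other way: the X ratio was 0.189 (0.126 to 0.278) against 0.318 on autosomes with replicate 1, and 0.667 (0.412 to 1.06) against 3.24 with replicate 2. H3K36me3 at 0 h had an X ratio of 0.889 (0.566 to 1.39) against 0.315 on autosomes, and the LSD1 antibody 1.33 (1.08 to 1.63) against 1.02 (0.994 to 1.04). The Pol II ratios on X, 1.09 and 1.11, were within counting error of the autosomal ones.

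**Figure D5:**
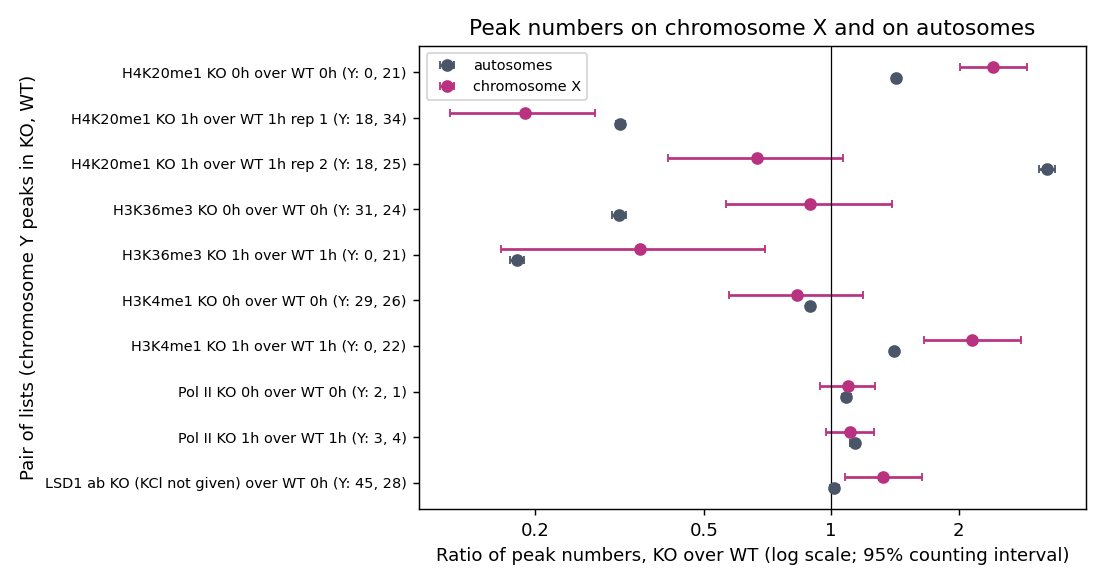
Ratio of peak numbers, KO over WT (log scale), on chromosome X and on autosomes for each pair of lists, with 95% counting intervals; the number of chromosome Y peaks in each list is in brackets. The X ratio exceeds the autosomal one in pairs with no Y peak in KO (H4K20me1 at 0 h and H3K4me1 at 1 h) and in pairs with Y peaks in both (H3K36me3 at 0 h and the LSD1 antibody), and Pol II genotypes follow the labels.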

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

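The autosomal ratio was planned as an alternative, but its use as a test of sex make-up, like the other tests of explanations in this part, was chosen after the data were seen; for the test that leaves out regions called with all 8 targets the bound was written before its own value was seen.

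H3K4me1 stands out because the genotype ratio of region numbers has opposite signs at the KCl times: KO over WT is -0.16 at 0 h and 0.49 at 1 h on the log2 scale. H3K36me3 stands out because its KCl ratio has opposite signs by genotype, 0.60 in WT and -0.22 in KO. Each ratio rests on 1 library per group, and the difference between the groups was not tested in either mark.

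No comparison was planned for chromosome Y by itself, and it stands out because 3 KO lists have no peak there: H4K20me1 at 0 h, H3K4me1 at 1 h and H3K36me3 at 1 h. Their WT partners have 21, 22 and 21, and the KO lists of the same marks at the other KCl time have 18, 29 and 31. In the other lists that are not Pol II the numbers run from 10 to 48, and in the Pol II lists from 1 to 4. The widest Y region of the H4K20me1 WT list at 0 h, at 2875771 to 2902534 of chromosome Y, is covered over at least 95.5% of its length in the 3 H4K20me1 lists at 1 h and not at all in KO at 0 h.

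The longer H4K20me1 list of the KO library at rest was weighed against 3 technical explanations and loss of LSD1n. Depth alone is not decided by the share of tags in regions, 1.88 times as high in KO. That share is counted inside the called regions, and their covered length was also 1.88 times as high. A longer list from any cause, depth included, could raise it. The KO library was the deeper, at 21256742 against 18494273 tags. Lists at equal depth were not compared, so depth stays open. For sex make-up as the whole cause, the log2 ratio on autosomes, 0.51, shows that the excess does not lie on X and Y. X held 412 of the 36291 KO regions and 171 of the 25429 WT regions, so this ratio could hardly come out otherwise. An effect of sex on autosomes was not tested. Stronger enrichment in the KO library could be part of it, and its test does not decide this. KO-only regions overlapped WT replicate 1 at 1 h 3.97 times as often as locally shifted regions, 21.7% against 5.45%. Lists of other targets give excesses of that size: H4K20me1 regions in WT at 0 h had from 2.14 times (Pol II) to 5.23 times (H3K4me2). The excess therefore does not show that KO-only regions are weakly marked in WT. Loss of LSD1n stays open and cannot be told apart from enrichment, since the test at 1 h does not decide it: the KO list, with 9022 regions, is 3.17 times as long as WT replicate 2, which shares its title prefix, and 0.317 times as long as replicate 1, which has another. A second pair of WT and KO libraries at rest would separate them.

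For the 3 KO lists without chromosome Y peaks, weak libraries are argued against, since 2 of the 3 have a higher share of tags in peaks than their WT partner. The library with the lowest such share of the 27 used, Flag-LSD1n at 0 h, has 48 Y peaks. Cultures without a Y chromosome, for example from female embryos, are a candidate explanation: for H4K20me1 at 0 h the X ratio is 2.41 (2.01 to 2.90) against 1.42 on autosomes, a test that replaced a first, circular form, and for H3K4me1 at 1 h it is 2.15 against 1.40. For H3K36me3 at 1 h the excess is within counting error (0.353, 0.166 to 0.699, against 0.181), and an X excess is seen without Y loss for H3K36me3 at 0 h (0.889 against 0.315) and the LSD1 antibody (1.33 against 1.02), so it is not specific. Whether chromosome Y alone was left out when the lists were made stays open. In a first form of the test the 3 lists had 44 peaks in the 7 windows of 1 Mb on X called in at least 12 of 15 histone lists. By its bound this form favoured it, and the definition was then changed. The windows from 73, 109, 139 and 166 Mb are held by all 15 lists, the 3 tested ones included. Peaks there were certain from the choice of windows, so the first form decides nothing. In the second form, 2 of the 6 windows held by all 12 histone lists with Y peaks, from 120 to 122 Mb, are empty in all 3 lists. The WT partners have 15, 17 and 14 peaks there. The 4 Pol II lists, of both labels, have 0 or 1 peaks in these windows and 1 to 4 on Y. Few peaks in both places are thus not particular to KO lists. The widest Y region of the H4K20me1 WT list at 0 h is called with 7 of the 8 targets. Whether the windows share sequence with Y was not tested.

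The longer Flag-LSD1n list after KCl was weighed against 3 technical explanations. Depth is argued against by total tags, which at 1 h were 0.824 of those at 0 h. Without sites that overlap peaks of all 8 targets the log2 ratio was 2.33, so the growth does not lie in those sites. They number 74 of 940 at 0 h and 77 of 4438 at 1 h, so this ratio could hardly come out otherwise. Weaker enrichment of the 0 h library may be part of it, and cannot be told apart from new binding: 23.7% (22.4 to 25.1) of the sites called at 1 h alone were already Flag-LSD1c sites at 0 h. That is far over the 0.120% of shifted sites and under the 52.6% (47.0 to 58.0) of sites called at both times; these shares leave out regions called with all 8 targets, and with them kept the values are 23.8% and 60.9%. Binding induced by KCl stays open as the biological explanation, and replicate libraries at 0 h would test it.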

How the results depend on the processing

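The alternatives that leave out regions called with all 8 targets, use the share of tags in peaks, use order in the list as rank, count peaks within 1 kb as shared, keep common regions among classes of sites, take site densities on autosomes, or average log2 numbers were chosen after seeing the data; all others were set before the data were examined. No paired analysis was possible because each comparison has at most 1 library per group and title prefix, so no prefix gives more than 1 pair. The KO and WT libraries of H4K20me1 at 1 h that share a prefix are compared by leaving out replicate 1, below. With 1 library in all groups but 1, no check for a library far from its group could be made. Ranking by width cannot be applied to sites of fixed size, so the alternative with wider peaks was run on 14 of the 24 ratios. The alternatives for gene lists were not run.

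Leaving out regions called with all 8 targets moved none of the 24 log2 ratios past its interval, and autosomes alone moved 2. No ratio changed sign when peaks were merged, wider peaks were taken or covered length was used. The cause was not tested for any change in this part. Leaving out each of the 2 H4K20me1 WT libraries at 1 h in turn gave ratios from -1.66 to 1.67 for KO over WT at 1 h and from -3.16 to 0.16 for WT 1 h over 0 h, so both directions rest on 1 library: without replicate 1 the first became 1.67, and without replicate 2 the second became 0.16.

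With peaks wider than the pooled median width the log2 ratios that moved were as follows. H4K20me1 KO over WT at 0 h 0.62, H3K36me3 KO over WT at 0 h -1.99, H3K36me3 KO over WT at 1 h -3.04 and H3K4me1 KO over WT at 0 h -0.22. H3K4me1 KO over WT at 1 h 0.65, H4K20me1 KO 1 h over 0 h -2.52, H3K36me3 WT 1 h over 0 h 0.77 and H3K4me1 WT 1 h over 0 h 0.49. H3K4me1 KO 1 h over 0 h 1.39, H3K4me2 WT 1 h over 0 h -0.52 and H4K20me1 WT KCl 1 h replicate 1 over replicate 2 3.93. With peaks within 5 kb merged, these moved. H4K20me1 KO over WT at 0 h 0.27, H3K36me3 KO over WT at 0 h -1.40, H3K36me3 KO over WT at 1 h -2.04 and H3K4me1 KO over WT at 0 h -0.12. H3K4me1 KO over WT at 1 h 0.43, LSD1 antibody KO over WT 0.10, H4K20me1 KO 1 h over 0 h -1.48 and H3K36me3 WT 1 h over 0 h 0.44. H3K4me1 WT 1 h over 0 h 0.21, H3K4me1 KO 1 h over 0 h 0.76, H3K4me2 WT 1 h over 0 h -0.16 and LSD1 antibody wild type 1 h over 0 h -0.21. Flag-LSD1n 1 h over 0 h 2.37, Flag-LSD1n over Flag-LSD1c at 0 h -2.20 and H4K20me1 WT KCl 1 h replicate 1 over replicate 2 2.56. By covered length, these moved. H4K20me1 KO over WT at 0 h 0.91, H3K36me3 KO over WT at 0 h -1.79, H3K36me3 KO over WT at 1 h -2.77 and H3K4me1 KO over WT at 0 h -0.21. H3K4me1 KO over WT at 1 h 0.64, H4K20me1 KO 1 h over 0 h -2.95, H3K36me3 WT 1 h over 0 h 0.72 and H3K4me1 WT 1 h over 0 h 0.44. H3K4me1 KO 1 h over 0 h 1.29, H3K4me2 WT 1 h over 0 h -0.41 and H4K20me1 WT KCl 1 h replicate 1 over replicate 2 4.22. On autosomes alone, these moved. Flag-LSD1n 1 h over 0 h 2.43 and Flag-LSD1n over Flag-LSD1c at 0 h -2.25. By the share of tags in peaks, Pol II KO over WT at 0 h and the LSD1 antibody changed sign, and these moved; the Pol II genotypes rest on labels that the names inside the lists contradict. H4K20me1 KO over WT at 0 h 0.91, H3K36me3 KO over WT at 0 h -1.26, H3K36me3 KO over WT at 1 h -2.33 and H3K4me1 KO over WT at 1 h 0.40. Pol II KO over WT at 0 h -0.0102, Pol II KO over WT at 1 h 0.13, LSD1 antibody KO over WT -0.36 and H4K20me1 KO 1 h over 0 h -2.72. H3K36me3 WT 1 h over 0 h 0.70, H3K36me3 KO 1 h over 0 h -0.37, H3K4me1 WT 1 h over 0 h 0.51 and H3K4me1 KO 1 h over 0 h 1.06. Pol II WT 1 h over 0 h 0.37, Pol II KO 1 h over 0 h 0.51, LSD1 antibody wild type 1 h over 0 h -0.27 and Flag-LSD1n 1 h over 0 h 1.93. Flag-LSD1c 1 h over 0 h 0.75, Flag-LSD1n over Flag-LSD1c at 0 h -1.67, Flag-LSD1n over Flag-LSD1c at 1 h -0.49 and H4K20me1 WT KCl 1 h replicate 1 over replicate 2 3.54.

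Shares of peaks fell in all 52 cases at an overlap of 50% of the peak, to between 0.140 and 0.941 of their value. In the pairs that follow, the first share is that of the first list. H4K20me1 WT 0 h and KO 0 h 67.6% and 16.7%, H4K20me1 WT 1 h replicate 1 and KO 1 h 4.003% and 68.1%, H4K20me1 WT 1 h replicate 2 and KO 1 h 54.0% and 5.15%. H3K36me3 WT 0 h and KO 0 h 5.11% and 26.9%, H3K36me3 WT 1 h and KO 1 h 2.61% and 35.4%, H3K4me1 WT 0 h and KO 0 h 29.5% and 35.7%. H3K4me1 WT 1 h and KO 1 h 55.7% and 30.0%, Pol II WT 0 h and KO 0 h 67.2% and 61.9%, Pol II WT 1 h and KO 1 h 69.0% and 61.0%. LSD1 LSD1n WT 0 h and LSD1n KO 35.8% and 35.0%, H4K20me1 WT 0 h and WT 1 h replicate 1 43.2% and 32.6%, H4K20me1 WT 0 h and WT 1 h replicate 2 0.912% and 74.8%. H4K20me1 KO 0 h and KO 1 h 1.55% and 80.5%, H3K36me3 WT 0 h and WT 1 h 24.5% and 12.1%, H3K36me3 KO 0 h and KO 1 h 8.41% and 10.7%. H3K4me1 WT 0 h and WT 1 h 46.3% and 30.7%, H3K4me1 KO 0 h and KO 1 h 64.3% and 17.9%, Pol II WT 0 h and WT 1 h 63.9% and 58.5%. Pol II KO 0 h and KO 1 h 67.8% and 59.6%, H3K4me2 WT 0 h and WT 1 h 44.2% and 64.3%, LSD1 wild type 0 h and wild type 1 h 13.1% and 16.1%. Flag-LSD1n 0 h and 1 h 33.7% and 7.14%, Flag-LSD1c 0 h and 1 h 21.1% and 15.1%, Flag-LSD1c 0 h and Flag-LSD1n 0 h 7.96% and 33.2%. Flag-LSD1c 1 h and Flag-LSD1n 1 h 17.6% and 21.8%, H4K20me1 WT 1 h replicate 2 and WT 1 h replicate 1 74.4% and 0.836%. With equal numbers of the highest-ranked peaks, 26 shares rose and 26 fell. H4K20me1 WT 0 h and KO 0 h 74.6% and 49.0%, H4K20me1 WT 1 h replicate 1 and KO 1 h 38.1% and 66.2%, H4K20me1 WT 1 h replicate 2 and KO 1 h 53.1% and 36.6%. H3K36me3 WT 0 h and KO 0 h 24.8% and 26.2%, H3K36me3 WT 1 h and KO 1 h 25.5% and 28.5%, H3K4me1 WT 0 h and KO 0 h 49.9% and 50.5%. H3K4me1 WT 1 h and KO 1 h 64.8% and 62.1%, Pol II WT 0 h and KO 0 h 73.1% and 73.1%, Pol II WT 1 h and KO 1 h 74.6% and 74.6%. H4K20me1 WT 0 h and WT 1 h replicate 1 57.3% and 52.8%, H4K20me1 WT 0 h and WT 1 h replicate 2 33.2% and 62.7%, H4K20me1 KO 0 h and KO 1 h 36.8% and 78.1%. H3K36me3 WT 0 h and WT 1 h 32.7% and 31.5%, H3K4me1 WT 0 h and WT 1 h 58.6% and 56.6%, H3K4me1 KO 0 h and KO 1 h 64.9% and 59.7%. Pol II WT 0 h and WT 1 h 71.0% and 71.0%, Pol II KO 0 h and KO 1 h 73.2% and 73.2%, H3K4me2 WT 0 h and WT 1 h 73.5% and 77.8%. LSD1 wild type 0 h and wild type 1 h 22.7% and 22.7%, Flag-LSD1n 0 h and 1 h 22.8% and 22.8%, Flag-LSD1c 0 h and 1 h 25.9% and 25.9%. Flag-LSD1c 0 h and Flag-LSD1n 0 h 24.8% and 24.8%, Flag-LSD1c 1 h and Flag-LSD1n 1 h 28.9% and 28.8%, H4K20me1 WT 1 h replicate 2 and WT 1 h replicate 1 60.0% and 31.2%. Counting peaks within 1 kb as shared raised all 20 shares of fixed-size lists. Pol II WT 0 h and KO 0 h 86.7% and 79.9%, Pol II WT 1 h and KO 1 h 87.4% and 77.7%, LSD1 LSD1n WT 0 h and LSD1n KO 62.6% and 59.4%. Pol II WT 0 h and WT 1 h 85.4% and 77.7%, Pol II KO 0 h and KO 1 h 85.7% and 75.2%, LSD1 wild type 0 h and wild type 1 h 48.0% and 53.0%. Flag-LSD1n 0 h and 1 h 61.6% and 13.2%, Flag-LSD1c 0 h and 1 h 58.5% and 43.1%, Flag-LSD1c 0 h and Flag-LSD1n 0 h 13.4% and 56.5%. Flag-LSD1c 1 h and Flag-LSD1n 1 h 49.6% and 60.3%. Shifts of 100 kb to 1 Mb lowered all 52 ratios to shifted lists, to between 0.408 and 0.720 of their value.

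Shares of LSD1 sites in marks fell in all 43 cases at an overlap of 50% of the site, and 36 moved. Flag-LSD1n 0 h sites: H3K4me2 61.5%, H3K4me1 20.9%, Pol II 26.1%, H4K20me1 20.4%. Flag-LSD1n 1 h sites: H3K4me2 53.4%, H3K4me1 18.5%, Pol II 33.2%, H4K20me1 replicate 1 9.85%, H4K20me1 replicate 2 6.80%. Flag-LSD1c 0 h sites: H3K4me2 77.9%, H3K4me1 11.1%, Pol II 34.3%, H4K20me1 12.3%. Flag-LSD1c 1 h sites: H3K4me2 52.7%, H3K4me1 18.9%, Pol II 41.3%, H4K20me1 replicate 1 7.94%, H4K20me1 replicate 2 5.58%. LSD1 wild type 0 h sites: H3K4me2 38.5%, H3K4me1 16.9%, Pol II 4.10%, H4K20me1 8.36%. LSD1 wild type 1 h sites: H3K4me2 27.0%, H3K4me1 25.7%, Pol II 17.5%, H4K20me1 replicate 1 5.03%, H4K20me1 replicate 2 1.87%, H3K36me3 1.14%. LSD1 LSD1n WT 0 h sites: H3K4me2 52.5%, H3K4me1 16.9%, Pol II 5.23%, H4K20me1 9.89%. LSD1 LSD1n KO sites: H3K4me2 45.7%, H3K4me1 15.3%, Pol II 5.37%, H4K20me1 8.99%. In the first part of each site list (50% of it), 35 rose and 8 fell. Flag-LSD1n 0 h sites: H3K4me2 54.7%, H3K4me1 37.0%, Pol II 33.4%, H4K20me1 35.1%, H3K36me3 33.0%. Flag-LSD1n 1 h sites: H3K4me2 56.6%, H4K20me1 replicate 1 18.2%, H4K20me1 replicate 2 12.3%, H3K36me3 6.80%. Flag-LSD1c 0 h sites: H3K4me2 83.2%, H3K4me1 15.2%, Pol II 55.8%, H4K20me1 19.1%, H3K36me3 8.01%. Flag-LSD1c 1 h sites: H3K4me1 20.5%, Pol II 65.4%, H4K20me1 replicate 1 12.9%, H4K20me1 replicate 2 9.23%, H3K36me3 5.51%. LSD1 wild type 0 h sites: H3K4me2 61.0%, Pol II 11.9%, H4K20me1 12.7%, H3K36me3 1.66%. LSD1 wild type 1 h sites: H3K4me2 35.5%, Pol II 40.3%, H4K20me1 replicate 2 3.15%, H3K36me3 1.77%. LSD1 LSD1n WT 0 h sites: H3K4me2 68.2%, Pol II 13.8%, H4K20me1 13.7%, H3K36me3 2.40%. LSD1 LSD1n KO sites: H3K4me2 66.1%, H3K4me1 19.9%, Pol II 12.9%, H4K20me1 13.9%, H3K36me3 2.63%. Without regions called with all 8 targets, 20 moved, all downward. Flag-LSD1n 0 h sites: H3K4me1 19.1%, Pol II 33.8%, H4K20me1 18.2%, H3K36me3 11.4%. Flag-LSD1n 1 h sites: H3K4me1 20.8%, H4K20me1 replicate 1 11.2%, H4K20me1 replicate 2 6.35%, H3K36me3 2.25%. Flag-LSD1c 0 h sites: H3K4me1 12.4%, H4K20me1 13.6%, H3K36me3 3.09%. Flag-LSD1c 1 h sites: H4K20me1 replicate 1 8.55%, H4K20me1 replicate 2 5.29%, H3K36me3 2.0%. LSD1 wild type 0 h sites: H3K36me3 0.899%. LSD1 wild type 1 h sites: H4K20me1 replicate 1 5.47%, H4K20me1 replicate 2 1.80%, H3K36me3 0.974%. LSD1 LSD1n WT 0 h sites: H3K36me3 1.13%. LSD1 LSD1n KO sites: H3K36me3 1.19%. Local shifts lowered all 43 ratios to shifted lists, and 1 passed under 1: wild type LSD1 sites at 1 h with H3K36me3, at 0.989.

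Chromosome X shares by covered length moved in 9 of 27 lists: H3K36me3 WT 0 h 0.548%, H3K36me3 WT 1 h 0.279%, H3K36me3 KO 0 h 2.01%, H3K4me1 KO 1 h 0.186%, H3K4me2 WT 0 h 0.504%, H3K4me2 WT 1 h 0.449%, H4K20me1 WT 0 h 0.396%, H4K20me1 KO 0 h 0.686% and H4K20me1 WT 1 h replicate 1 0.322%. The counting interval of the LSD1 antibody ratio of KO over WT includes 0 in the lists as deposited. Libraries ran from 6990017 to 34859557 tags and were called at thresholds of 11 to 26 tags per peak, so list lengths do not rest on equal depth.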

Other observations

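The test of the hypothesis in this part was set before its result was seen, but the way its label is decided was changed after it; the counts on contigs and common regions and the autosomal ratios were chosen after the results were seen.

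The 4 Pol II lists hold 76 to 88 peaks each on unplaced contigs, and the other 23 lists hold none. The regions called with all 8 targets number 434, cover 2.98 Mb and lie most often on chromosome 11 (46 regions) and chromosome 2 (45 regions); 37 of them are in all 27 lists. Among sites shared by both lists of a comparison, those placed first and second in both Flag-LSD1c lists, on chromosome 9 (35112824 to 35113024) and chromosome 2 (98502813 to 98503013), are called with all 8 targets.

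If LSD1n removed H4K20me1 at its sites, LSD1n sites might be denser in regions that carry the mark in KO and not in WT at rest than in those with the mark in WT alone, and more so than LSD1c sites. The ratio of densities for LSD1n sites at 1 h was 0.172 (0.123 to 0.242), with 74 sites in 20.9 Mb of KO-only and 72 in 3.51 Mb of WT-only regions. LSD1c sites at 1 h gave 0.204 (0.145 to 0.289), so the intervals overlap. Sites at 0 h rank the isoforms the other way, 0.175 (0.113 to 0.273) for LSD1n and 0.145 (0.105 to 0.202) for LSD1c, again with overlapping intervals. These ratios are tied to chromosome Y, since the KO list at 0 h has no region there and every WT region on Y counts as WT-only, while the Flag lists hold many Y sites. On autosomes the ratios are 0.603 (0.313 to 1.25) at 0 h and 0.270 (0.184 to 0.401) at 1 h for LSD1n, and 0.216 (0.150 to 0.314) and 0.251 (0.174 to 0.365) for LSD1c. LSD1n sites at 0 h were thus not shown to be sparser in KO-only regions on autosomes, where 12 sites lay in WT-only regions. No point value is above 1, the direction in which the hypothesis might show, though the interval of that ratio reaches 1.25. The bound set beforehand, a ratio no higher than that of LSD1c, is met by the point values at 1 h on all chromosomes, though not by more than their intervals, and is not met at 0 h or on autosomes. The label rests on the sites at 1 h and was decided in 3 ways: by point values and then by a 2-part rule, which both argued against the hypothesis, and last by intervals, which leaves it open. WT-only regions are narrower (median 501 against 629 bp), which was not corrected for.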
